A study of Homo sapiens with 3 samples.

How the data were processed

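K562 cells expressing dCas9-KRAB were infected with a pooled lentiviral sgRNA library, selected with puromycin for 5 days and passaged in de-lipidated medium. Genomic DNA was taken before treatment (T0) and after 6 days with DMSO or 1 µM myriocin, and the sgRNA cassettes were amplified and sequenced. There is 1 library per condition; whether replicate cultures were pooled, the number of cell doublings and the rule for counting a read are not given in the sources used here. The deposited table holds raw read counts per sgRNA in 3 columns, per the file headers, with no normalization. The submitters' processing notes name bcl2fastq 2.17.1.14, Bowtie without a version and the build hg19. Total reads were 98835407 for T0, 66821048 for the DMSO endpoint and 89989770 for the myriocin endpoint; 1579, 1741 and 1881 of 202542 sgRNAs had 0 reads, and the most abundant sgRNA had 3918, 2936 and 17560 reads. Control sgRNAs took 4.70%, 4.76% and 4.72% of reads.

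Each sgRNA was assigned to its gene and promoter from the library's identifiers, which give a position but no chromosome; positions are read as hg19. The pool comes in 7 sublibraries, each with its own control sgRNAs, and 3153 genes have more than 1 promoter. Gene symbols were compared with a table of GRCh38.p14 gene names, which was used for current symbols and for chromosomes when listing neighbouring promoters within 1 kb; 15900 symbols (99.5%) matched, 14889 as the current symbol and the others as a synonym. Symbols are printed as the library gives them.

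For each comparison the log2 ratio of reads plus a pseudocount of 1 was computed per sgRNA with 50 or more reads in at least 1 of the compared libraries, and the median over control sgRNAs was subtracted. An sgRNA with under 50 reads in the denominator library thus entered only with 50 or more in the numerator. For myriocin against DMSO this can raise the values of promoters depleted in DMSO. A promoter's value is the mean over its sgRNAs with its SE, for promoters with 3 or more sgRNAs. Its sgRNAs were compared with 9550 (myriocin against DMSO), 9582 (DMSO against T0) or 9610 (myriocin against T0) control sgRNAs by an exact two-sided Mann-Whitney test with ties resolved against a difference, adjusted by Benjamini-Hochberg over all promoters of the comparison; the threshold was an adjusted p of 0.05. A gene with more than 1 promoter is described by the promoter with the smallest p, so the promoter can differ between comparisons. The p-values compare sgRNAs within these libraries. Counting error alone gives an SD of 0.11, 0.11 and 0.10 in log2 ratio for the 3 comparisons, against 0.52, 0.27 and 0.53 observed over control sgRNAs. Splitting the spread of control sgRNAs into a part per library put 9.28% of their sum in T0, 13.6% in DMSO and 77.1% in myriocin.

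Random sets of 10 control sgRNAs were tested as promoters are, and 7, 23 and 20 of 20000 sets passed the threshold of their comparison. These sets come from the controls themselves, so the number passing follows from the p cutoff. It checks how the test was computed and does not measure false calls among promoters. Means of disjoint subsets of each promoter's sgRNAs, taken alternately, correlated across promoters at r = 0.20, 0.42 and 0.28 (Spearman 0.10, 0.17 and 0.15); promoters are not independent replicates. The pipeline was tested on simulated counts in which promoters with 10 sgRNAs were changed by a known amount. With every sgRNA active at a log2 change of 0.5, 38%, 99% and 31% of changed promoters were recovered in the 3 comparisons, and 100% at 1. With 5 of 10 sgRNAs active at 1, 1%, 3% and 1% were recovered. Benjamini-Hochberg was applied within each simulated run, and the runs with 5 active sgRNAs had 1, 4 and 1 calls in all. Their p cutoff was thus stricter than in the data, where 118, 434 and 290 promoters passed. The percentages for 5 active sgRNAs can therefore understate recovery at the cutoffs of the data.

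Before the data were examined, 40 gene lists were fixed from textbook membership. A list is described by the median of its genes, as a percentile among 10000 random lists of the same size matched on read count per sgRNA in the denominator library (10 bins), and for myriocin against DMSO also matched on the DMSO change from T0. The latter match shares the DMSO library with the ratio, so it tends to lower the percentiles of lists depleted in DMSO. Calls are counted over all promoters and adjusted over the list alone. Another 10 lists were added after the data were seen. The genes named were set by a rule fixed before the data were examined. For myriocin against DMSO these are the 12 largest values each way past the threshold, the 3 members with the largest absolute value in each list described, and every measured member of the serine palmitoyltransferase, ORMDL, and ceramide transfer and sphingomyelin synthesis lists. For DMSO against T0 they are the 10 largest each way and the 3 largest members per list, and for myriocin against T0 the 5 largest each way. Genes with another promoter within 1 kb were kept and the neighbour is named for the genes with the largest values. Values of some list members are not reported.

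The alternatives chosen before the data were examined were no read minimum or minimums of 20 and 100 reads, a pseudocount of 10, scaling to total reads, a permutation test of the mean against 100000 random control sets, olfactory receptor sgRNAs as the background, leaving out each promoter's strongest sgRNA, the mean of the 3 strongest sgRNAs, an adjusted p of 0.01, and the residual of the myriocin change on the DMSO change. Centring and ranking against the controls of the promoter's own sublibrary, and leaving out 2197 sgRNAs whose sequence occurs more than once, were added after the data were seen. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.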

Results

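A pool of single guide RNAs (sgRNAs) was read out in K562, an erythroleukaemia cell line, carrying dCas9-KRAB, a repressor that the sgRNAs direct to promoters (CRISPR interference). The question was which knockdowns change how cells grow when myriocin, an inhibitor of serine palmitoyltransferase, blocks the first step of sphingolipid synthesis. One library was sequenced from each of 3 populations in de-lipidated medium: T0 at day 5 after infection, and endpoints after 6 days with DMSO or with 1 µM myriocin. The libraries held 98835407, 66821048 and 89989770 reads, with medians of 456, 305 and 393 reads per sgRNA. The pool targeted 20899 promoters of 15975 genes and held 9819 non-targeting control sgRNAs. Values are mean log2 ratios over the sgRNAs of a promoter relative to the median control sgRNA, ± SE over sgRNAs, with the number of sgRNAs as n. They are not divided by cell doublings. Each adjusted p is from an exact two-sided Mann-Whitney test of those sgRNAs against the control sgRNAs, adjusted by Benjamini-Hochberg over all promoters. No condition has a replicate library, so errors and p-values describe sgRNAs within these libraries and not the variation between cultures.

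Knockdown of VPS29, EPG5, SPI1 and WDR7 gave the largest increases past the test at the myriocin endpoint over the DMSO endpoint. VPS29, a subunit shared by the retromer and retriever endosomal recycling complexes, gave the highest value, 2.92 ± 0.37 (n = 10), a mean 7.55-fold higher (adjusted p = 2.85e-12, 10 of 10 sgRNAs above 0). EPG5, a tether between autophagosomes and late endosomes or lysosomes, rose by 2.40 ± 0.26 (n = 10; adjusted p = 2.21e-17, 10 of 10). SPI1, which encodes the myeloid transcription factor PU.1, rose by 2.18 ± 0.29 (n = 10; adjusted p = 2.65e-09, 10 of 10). WDR7, a rabconnectin-3 subunit that acts with the vacuolar proton pump, rose by 1.76 ± 0.22 (n = 10; adjusted p = 2.65e-09, 10 of 10). The sgRNAs of VPS29 lie at hg19 positions 110939630 to 110939912, those of EPG5 at 43546984 to 43547263, those of SPI1 at 47399851 to 47400154 and those of WDR7 at 54318628 to 54318914. VPS29 has the promoter of RAD9B within 1 kb, whose own sgRNAs gave 0.68 and did not pass the exact test (adjusted p = 0.598). WDR7 has the promoter of TXNL1 within 1 kb.

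The other 8 of the 12 largest increases were 1.72 ± 0.32 for WDR11, a vesicle-tethering protein of the trans-Golgi, 1.69 ± 0.33 for CCDC22 and 1.65 ± 0.22 for COMMD10, both of the Commander endosomal recycling complex, 1.57 ± 0.24 for ELOVL6, which elongates palmitate to stearate, 1.56 ± 0.33 for LSM2 and 1.54 ± 0.49 for LSM6, both Sm-like proteins of RNA processing, 1.54 ± 0.35 for ATP5F1, a subunit of the mitochondrial ATP synthase, and 1.53 ± 0.28 for PTPN1, a tyrosine phosphatase. Their exact tests gave adjusted p from 2.27e-09 (COMMD10, n = 8) to 0.0169 (LSM6, n = 7). ATP5F1 has the promoter of WDR77 within 1 kb, which itself rose by 0.93. In all, 79 genes rose and 37 fell.

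Of the knockdowns that passed the test as lower under myriocin, PI4K2B, a PI4-kinase, fell most, by 1.53 ± 0.41 (n = 9; exact test, adjusted p = 0.000312, 9 of 9 sgRNAs at or below 0), a mean 2.89-fold lower than at the DMSO endpoint. SREBF2, which encodes the transcription factor that induces cholesterol synthesis, fell by 1.52 ± 0.32 (n = 10; adjusted p = 4.81e-05), and FASN, fatty acid synthase, fell by 1.49 ± 0.44 (n = 10; adjusted p = 0.0419). SEC22B, a SNARE of traffic between endoplasmic reticulum and Golgi, fell by 1.33 ± 0.39 over 6 sgRNAs (exact test, adjusted p = 0.0102). LAPTM5, a lysosomal membrane protein, fell by 1.17 ± 0.30, TMED10, a p24 cargo receptor, by 1.15 ± 0.17, and USE1, a SNARE of the endoplasmic reticulum, by 1.09 ± 0.21. The rest of the 12 largest decreases were −1.06 ± 0.22 for TRAPPC13, −1.01 ± 0.35 for CLTA, a clathrin light chain, −1.001 ± 0.30 for SCYL2, a clathrin-binding protein, −0.99 ± 0.26 for PI4KB, and −0.95 ± 0.29 for AGPAT1, an acyltransferase of phosphatidic acid synthesis. TRAPPC13 has the promoter of TRIM23 within 1 kb (−0.43, exact test, adjusted p = 0.612), and SCYL2 that of DEPDC4.

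**Figure D1:**
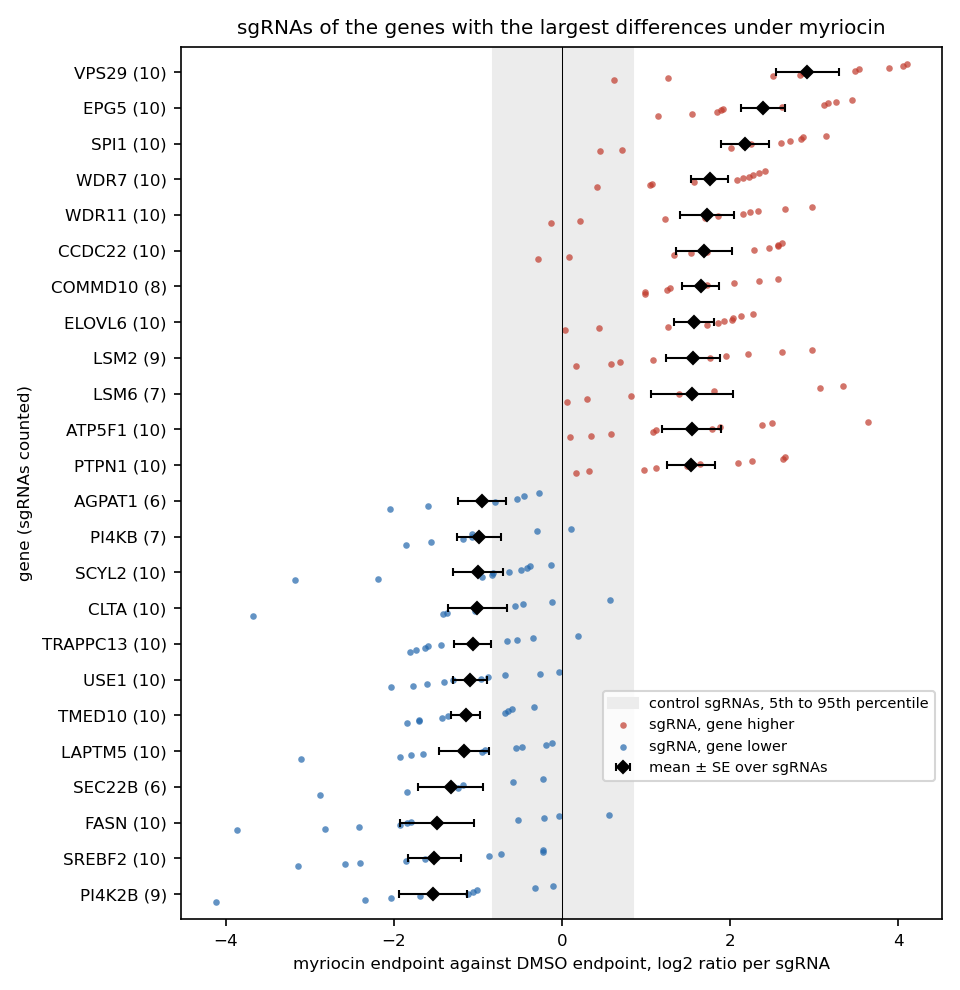
Each point is 1 sgRNA's log2 ratio of the myriocin to the DMSO endpoint for the 12 genes with the largest increase and the 12 with the largest decrease, with the mean ± SE over sgRNAs as a diamond. The band spans the 5th to 95th percentile of control sgRNAs, −0.82 to 0.84, and all 10 VPS29 sgRNAs lie above 0.

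Within sphingolipid synthesis, knockdown of SPTLC1, of the drug's own target complex, and of KDSR, the next enzyme, gave higher values under myriocin. Of 4 measured serine palmitoyltransferase genes, SPTLC1 rose by 0.90 ± 0.21 (n = 10; adjusted p = 0.00395, 10 of 10 sgRNAs), and it was the 1 call adjusted over the list alone. The others did not pass: SPTLC3 0.37 ± 0.17, SPTLC2 0.28 ± 0.22 and SPTSSA −0.02 ± 0.26. The list's median was 0.32, at percentile 99.8 of 10000 random lists of the same size and similar read count. KDSR, which reduces the product of serine palmitoyltransferase, rose by 1.44 ± 0.33 (n = 10; adjusted p = 3.68e-05, 10 of 10). It was the 1 gene called among 14 ceramide synthesis genes, also adjusted over the list alone, where ELOVL1 stood at −0.45 ± 0.31 and DEGS1 at 0.34 ± 0.28. The ORMDL genes, whose products restrain serine palmitoyltransferase, had a median of 0.42 (percentile 99.5), but none of the 3 passed either adjustment: ORMDL2 0.49 ± 0.32, ORMDL3 0.42 ± 0.31 and ORMDL1 0.24 ± 0.16. ORMDL1 and ORMDL2 have the promoters of PMS1 and SARNP within 1 kb.

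Later steps of the pathway were near the control level. None of 7 genes of ceramide transfer and sphingomyelin synthesis passed the test over all promoters or adjusted over the list alone (median −0.06, percentile 25.4). COL4A3BP, the ceramide transfer protein, stood at −0.28 ± 0.22 (n = 10), PPM1L at −0.23 ± 0.18, SGMS1 at −0.10 ± 0.16, SAMD8 at −0.06 ± 0.17, VAPA at −0.05 ± 0.40, VAPB at −0.04 ± 0.17 and SGMS2 at 0.24 ± 0.10. Among 15 glycosphingolipid genes (median 0.02) the 1 call was adjusted over the list alone, TM9SF2 at 0.74 ± 0.23. None of 26 genes of sphingolipid breakdown and salvage passed either adjustment (median 0.01), with SPHK2 at −0.57, GBA2 at −0.40 and ALDH3A2 at 0.35.

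Cholesterol synthesis was the lipid list with the lowest median under myriocin. Of its 21 genes, 17 lay below 0, the median was −0.30, and the percentile was 0 both among random lists of similar read count and among lists matched on growth in DMSO. Over all promoters 2 of the genes fell, and 8 fell adjusted over the list alone. SC5D, a sterol desaturase named after its value was seen, fell by 0.72 ± 0.14 (exact test, adjusted p = 0.00685). HMGCS1 at −1.68 ± 0.55 and CYP51A1 at −1.49 ± 0.57 had wide errors and did not pass over all promoters. In the SREBP pathway SREBF2 was the 1 of 10 genes to change, also adjusted over the list alone, beside MBTPS2 at −0.58 ± 0.39 and INSIG2 at 0.44 ± 0.17; the list's median of 0.08 and mean of −0.09 differ in sign.

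Of 20 fatty acid genes, ELOVL6 rose and FASN fell; adjusted over the list alone, 1 rose and 2 fell, and ELOVL5 stood at −1.03 ± 0.41. Of 25 genes of phosphatidylinositol transfer and PI4-kinases (median −0.15, percentile 0.07), PI4K2B and PI4KB fell, and none rose. Adjusted over the list alone, 2 fell and 1 rose; SACM1L, a phosphatase of the PI4-kinase product, stood at 1.05 ± 0.30. Of 30 phospholipid synthesis genes, AGPAT1 fell while AGPAT2, which has the same activity and was named after its value was seen, rose by 0.82 ± 0.10 (n = 10; adjusted p = 7.42e-05); adjusted over the list alone, 2 rose and 1 fell. ETNK1 and PCYT2, of phosphatidylethanolamine synthesis, stood at 1.05 ± 0.37 and 0.97 ± 0.40 without passing. The 11 genes of serine synthesis and one-carbon metabolism had a median of 0.15 (percentile 98.1, and 92.6 among lists matched on growth in DMSO) and no call by either adjustment.

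The V-ATPase, the proton pump of endosomes and lysosomes, had 13 of 16 genes above 0 and a median of 0.34, at percentile 100 of random lists. ATP6AP1 rose by 1.39 ± 0.29 (n = 10), ATP6V1A by 1.33 ± 0.34 (n = 9) and ATP6AP2 by 1.28 ± 0.31 (n = 10). ATP6V1G1 (1.23 ± 0.34) and ATP6V1C1 (1.06 ± 0.22), named after their values were seen, made 5 calls, against 6 adjusted over the list alone. Among 23 genes of retromer, HOPS and endosome fusion, VPS29 and RAB7A (1.06 ± 0.33) rose, with VPS35 at 1.47 ± 0.49; adjusted over the list alone, 3 rose and 4 fell, and the list's median was 0.04. The COPI coat of Golgi to endoplasmic reticulum traffic had a median of 0.27 (percentile 99.9) with no call among 11 genes and 3 higher adjusted over the list alone; COPB1 stood at 0.68 ± 0.23, COPE at 0.51 and COPG2 at 0.49.

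The COPII coat, which carries cargo out of the endoplasmic reticulum, had a median of −0.27 over 15 genes, at percentile 0. SEC23B fell by 0.92 ± 0.32 (exact test, adjusted p = 0.0482) and SEC24A, named after its value was seen, by 0.59 ± 0.13 (adjusted p = 0.0354), while SEC23A rose by 0.69 ± 0.08 (adjusted p = 0.00061, 10 of 10 sgRNAs). SEC24C stood at −0.83 ± 0.28, and adjusted over the list alone 6 fell and 1 rose. Of 14 TRAPP tethering genes (median −0.07, percentile 11.2), TRAPPC13 and TRAPPC8 (−0.74 ± 0.15) fell, also adjusted over the list alone, and TRAPPC12 stood at −0.74 ± 0.36. Of 6 GARP and EARP genes (median −0.23, percentile 1.49), TSSC1 fell by 0.67 ± 0.18 and was the 1 call adjusted over the list alone, with VPS54 at −0.80 ± 0.45 and VPS53 at −0.51 ± 0.23. The 8 genes of the COG complex, a Golgi tether, had a median of −0.23 (percentile 0.3) and no call by either adjustment, with COG5 at −0.39, COG4 at −0.31 and COG1 at −0.27. The flippases and scramblases had a median of 0.16 (percentile 99.3) and no call among 17 genes, with 1 higher adjusted over the list alone and TMEM30A, a subunit of flippases, at 1.28 ± 0.65.

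**Figure D2:**
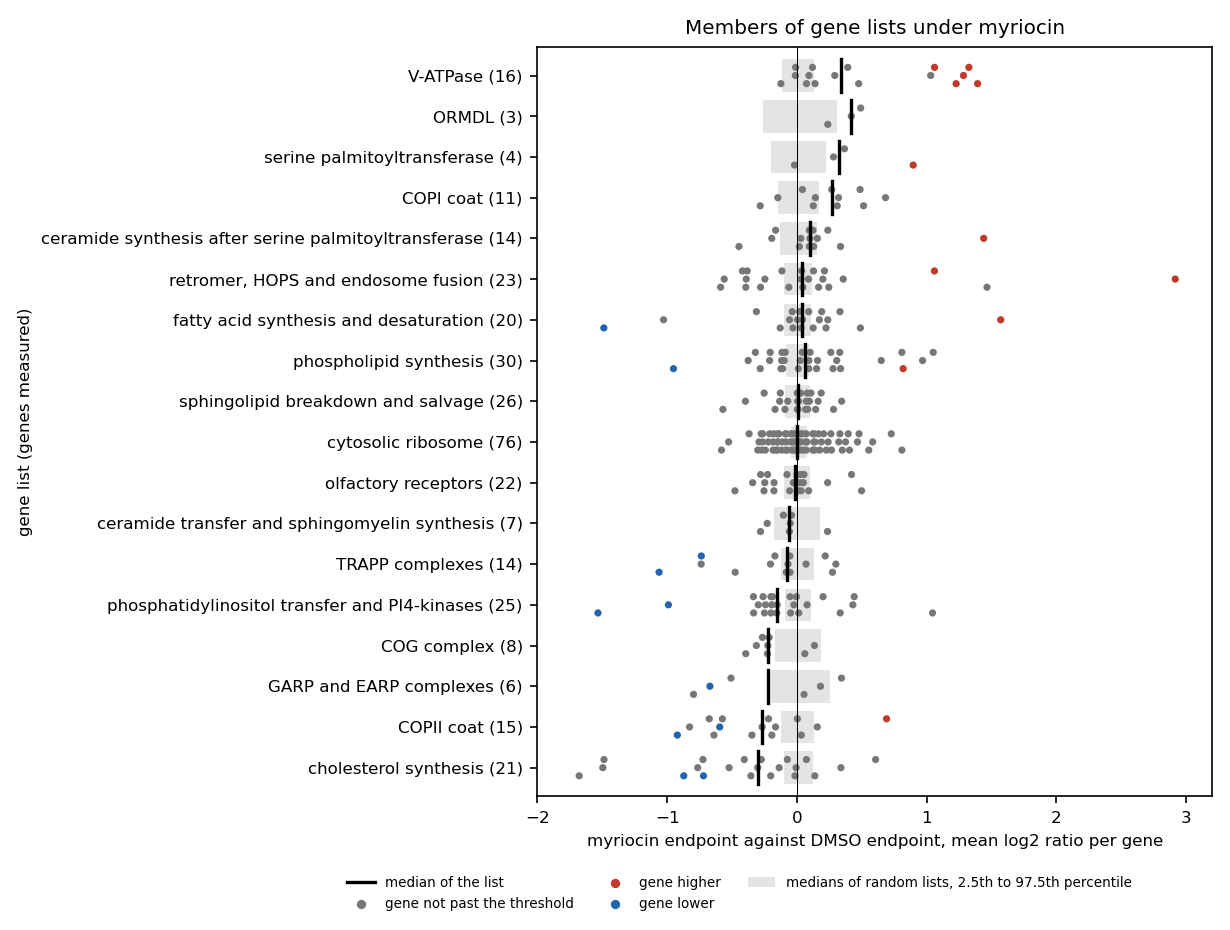
Each point is a gene's mean log2 ratio of the myriocin to the DMSO endpoint, by gene list, with the list's median as a bar and the central 95% of the medians of random lists shaded. The V-ATPase median of 0.34 lies above its band and the cholesterol synthesis median of −0.30 below it.

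Among lists of other cell functions, medians were 0.09 for GPI anchor synthesis (percentile 96.6), 0.13 for N-glycosylation (percentile 98.9), −0.11 for mTORC1 and its regulators (percentile 0.86), 0.03 for mTORC2 and AKT, −0.09 for the ER membrane complex and tail-anchor insertion, −0.07 for ER-associated degradation and the unfolded protein response, −0.06 for drug transporters, 0.08 for ER shaping, 0.05 for peroxisome biogenesis and 0.07 for UFMylation, and none of these had a call over all promoters, with 0 to 2 calls adjusted over the list alone. The mean of the ER membrane complex list, 0.01, differs in sign from its median. Of 31 DNA replication genes (median 0.14, percentile 99.5), RRM2, of ribonucleotide reductase, rose by 0.72 ± 0.19, and of 26 spliceosome genes PRPF8 rose by 1.21 ± 0.38; adjusted over the list alone, 1 and 2 rose. No gene passed among 76 of the cytosolic ribosome (38 above 0 and 38 below), 71 of the mitochondrial ribosome, 37 of respiratory complex I (median −0.06, 1 lower adjusted over the list alone) or 31 of the proteasome (median 0.12, percentile 99.1, 2 higher adjusted over the list alone). Among lists matched on growth in DMSO, DNA replication, the proteasome and N-glycosylation were at percentiles 92.0, 88.5 and 97.46, inside the central 95%, and the cytosolic ribosome moved out of it from percentile 27.6 to 1.12, respiratory complex I from 5.14 to 0.95, GPI anchor synthesis from 96.6 to 98.3 and the K562 drivers and erythroid factors from 2.62 to 1.29. Of 23 K562 drivers and erythroid factors, SHOC2 fell by 0.83 ± 0.22 and NFE2 by 0.72 ± 0.14 (3 lower and 1 higher adjusted over the list alone); SHOC2 has the promoter of BBIP1 within 1 kb. Of 22 growth suppressors, PTPN1 and STAG2 (0.84 ± 0.22), a cohesin subunit, rose (3 adjusted over the list alone), while the list had a median of −0.01 and a mean of 0.11. The 22 olfactory receptor genes, not expressed in most tissues, had a median of −0.01 and 8 keratin-associated genes 0.05, with no call in either and 1 lower olfactory receptor adjusted over the list alone.

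At an adjusted p of 0.05, 118 of 20229 promoters differed between the endpoints, 81 higher and 37 lower, and 1630 promoters passed at an unadjusted p under 0.05. Of 20000 sets of 10 control sgRNAs, 7 passed at the same p as the 118. That number follows from the p cutoff, here and in the other comparisons, and is no measure of false calls among promoters. The control sgRNAs had an SD of 0.52, against 0.11 from counting alone, and of their variance summed over the 3 libraries 77.1% lay in the myriocin library. Without each promoter's strongest sgRNA 52 promoters passed, and of the genes named by the fixed rule FASN, PI4KB, AGPAT1, CLTA, SEC22B, LSM6, ATP6V1A, RAB7A, SEC23B, TSSC1, RRM2, PRPF8 and STAG2 were no longer called; the mean of the 3 strongest sgRNAs ended the calls of SEC23A, NFE2, SHOC2, TRAPPC8, AGPAT1, PI4KB, RRM2, STAG2 and TSSC1, and olfactory receptor sgRNAs as the background those of FASN, PI4KB, AGPAT1, CLTA, SEC23B and TSSC1.

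Without drug, from T0 to the DMSO endpoint, the largest decreases past the test were those of MRPS2, CLNS1A, CAD and SUPV3L1. MRPS2, of the mitochondrial ribosome, fell by 2.39 ± 0.63 over 3 sgRNAs (exact test, adjusted p = 1.89e-06), with the promoter of C9orf116 within 1 kb. CLNS1A, a chaperone of spliceosomal Sm proteins, fell by 2.08 ± 0.19 over 7 sgRNAs (exact test, adjusted p = 3.86e-16, 0 of 7 above 0), a mean 4.22-fold. CAD, of pyrimidine synthesis, fell by 1.81 ± 0.46 (n = 9) and SUPV3L1, a mitochondrial RNA helicase, by 1.59 ± 0.56 (n = 9). The other 6 of the 10 largest decreases were −1.57 ± 0.35 for CYB5B, −1.56 ± 0.44 for CASP8AP2, −1.52 ± 0.43 for CENPI and −1.49 ± 0.38 for HJURP, both centromere proteins, and −1.49 ± 0.39 for HSD17B10 and −1.48 ± 0.51 for TRMT10C, both of mitochondrial RNase P.

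Increases without drug were fewer and smaller. PLEKHA1 had the highest value, 0.60 ± 0.14 (n = 10; adjusted p = 0.00049), followed by MAGED2 at 0.56 ± 0.14, SPI1 at 0.46 ± 0.09, PLEKHH3 at 0.41 ± 0.13 and STAT5A, a signal transducer downstream of cytokine receptors and kinases, at 0.34 ± 0.08. NOA1, ASPHD1, ITSN2, TRPV2 and PPP2R5D rose by 0.28 to 0.32; NOA1 has the promoter of POLR2B within 1 kb.

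The lists of core cell functions were depleted together. The median was −0.37 for the mitochondrial ribosome, where 10 of 71 genes fell (18 adjusted over the list alone), among them MRPS5 (−1.36 ± 0.44) and MRPL22 (−1.34 ± 0.58). It was −0.34 for the spliceosome, where 8 of 26 fell (9 adjusted over the list alone), led by AQR (−0.95 ± 0.30), SNRPD1 (−0.91 ± 0.23) and SNRPD3 (−0.72 ± 0.24). It was −0.33 for the cytosolic ribosome, with 16 of 76 lower (35 adjusted over the list alone), including RPS4X (−1.01 ± 0.38) and RPL21 (−0.98 ± 0.19). DNA replication had a median of −0.29 with 9 of 31 lower (12 adjusted over the list alone), led by GINS1 (−1.10 ± 0.30), RRM1 (−0.89 ± 0.29) and MCM3 (−0.86 ± 0.27), and the proteasome −0.21 with 4 of 31 lower (7 adjusted over the list alone), led by PSMD4 (−0.89 ± 0.40), PSMA1 (−0.73 ± 0.18) and PSMA5 (−0.57 ± 0.21). Respiratory complex I had a median of −0.17, with 4 of 37 lower (6 adjusted over the list alone), NDUFC1 (−0.53 ± 0.12) among them. Each of these medians was at percentile 0.

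Cholesterol synthesis was depleted in the de-lipidated medium even without myriocin. Its median was −0.31 (percentile 0), and 3 of 21 genes fell, 9 adjusted over the list alone: PMVK by 1.32 ± 0.33 (exact test, adjusted p = 1.21e-05), HMGCS1 by 1.27 ± 0.25 (adjusted p = 3.08e-10) and FDPS by 0.90 ± 0.23 (adjusted p = 9.21e-06) among them. Of 14 ceramide synthesis genes (median −0.05), HSD17B12 fell by 1.12 ± 0.28 and PTPLB by 0.97 ± 0.20, both of the very-long-chain fatty acid cycle, with 4 lower adjusted over the list alone. No serine palmitoyltransferase gene passed by either adjustment (median −0.13, percentile 6.41). Of 23 K562 drivers and erythroid factors, 4 fell and 1 rose (8 and 3 adjusted over the list alone), with GATA1 at −1.07 ± 0.30, LDB1 at −0.76 ± 0.28 and STAT5A as the increase. Growth suppressors and olfactory receptors each had a median of 0.06, at percentiles 99.97 and 99.93, and neither had a call; 1 growth suppressor rose adjusted over the list alone.

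In this comparison 434 of 20237 promoters differed, 23 higher and 411 lower, and 23 of 20000 control sets passed at the same p; 2084 promoters passed at an unadjusted p under 0.05. Of the called promoters, 17.4% have another gene's promoter within 1 kb, against 11.8% of all promoters; the control SD was 0.27. With the mean of the 3 strongest sgRNAs 8 promoters were higher and SPI1, STAT5A, NOA1, ASPHD1, ITSN2, TRPV2, PPP2R5D and NDUFC1 were no longer called, and at a minimum of 100 reads AQR, GATA1, LDB1, PSMA5, NOA1 and PLEKHH3 were not called. Without each promoter's strongest sgRNA 244 promoters passed, and AQR, SNRPD3, GINS1, MCM3, PSMA5, NDUFC1, LDB1, NOA1, ASPHD1, ITSN2 and PPP2R5D were no longer called.

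From T0 to the myriocin endpoint the lowest value was that of HMGCS1, the synthase at the start of the sterol pathway, which fell by 3.02 ± 0.54 (n = 10; adjusted p = 1.79e-05), a mean 8.11-fold. HJURP fell by 2.39 ± 0.58, SREBF2 by 1.91 ± 0.44, SEC22B by 1.86 ± 0.43 and TPX2, a spindle assembly factor, by 1.84 ± 0.52. SPI1 rose most, by 2.65 ± 0.34 (n = 10; adjusted p = 2.77e-11, 10 of 10 sgRNAs), a mean 6.28-fold, followed by EPG5 at 2.11 ± 0.23, VPS29 at 1.84 ± 0.22, CCDC22 at 1.72 ± 0.37 and PTPN1 at 1.67 ± 0.29. By list, 6 of 21 cholesterol synthesis genes fell (median −0.78; 13 adjusted over the list alone) and 3 V-ATPase genes rose (median 0.34; 6 adjusted over the list alone). Of 15 COPII genes 3 fell and 1 rose (median −0.48; 6 and 1 adjusted over the list alone). Of the cytosolic ribosome 3 fell (median −0.35; 9 adjusted over the list alone) and of the mitochondrial ribosome 5 fell (median −0.31; 23 adjusted over the list alone), while no spliceosome or proteasome gene passed (medians −0.21 and −0.06; 2 and 1 lower adjusted over the list alone).

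**Figure D3:**
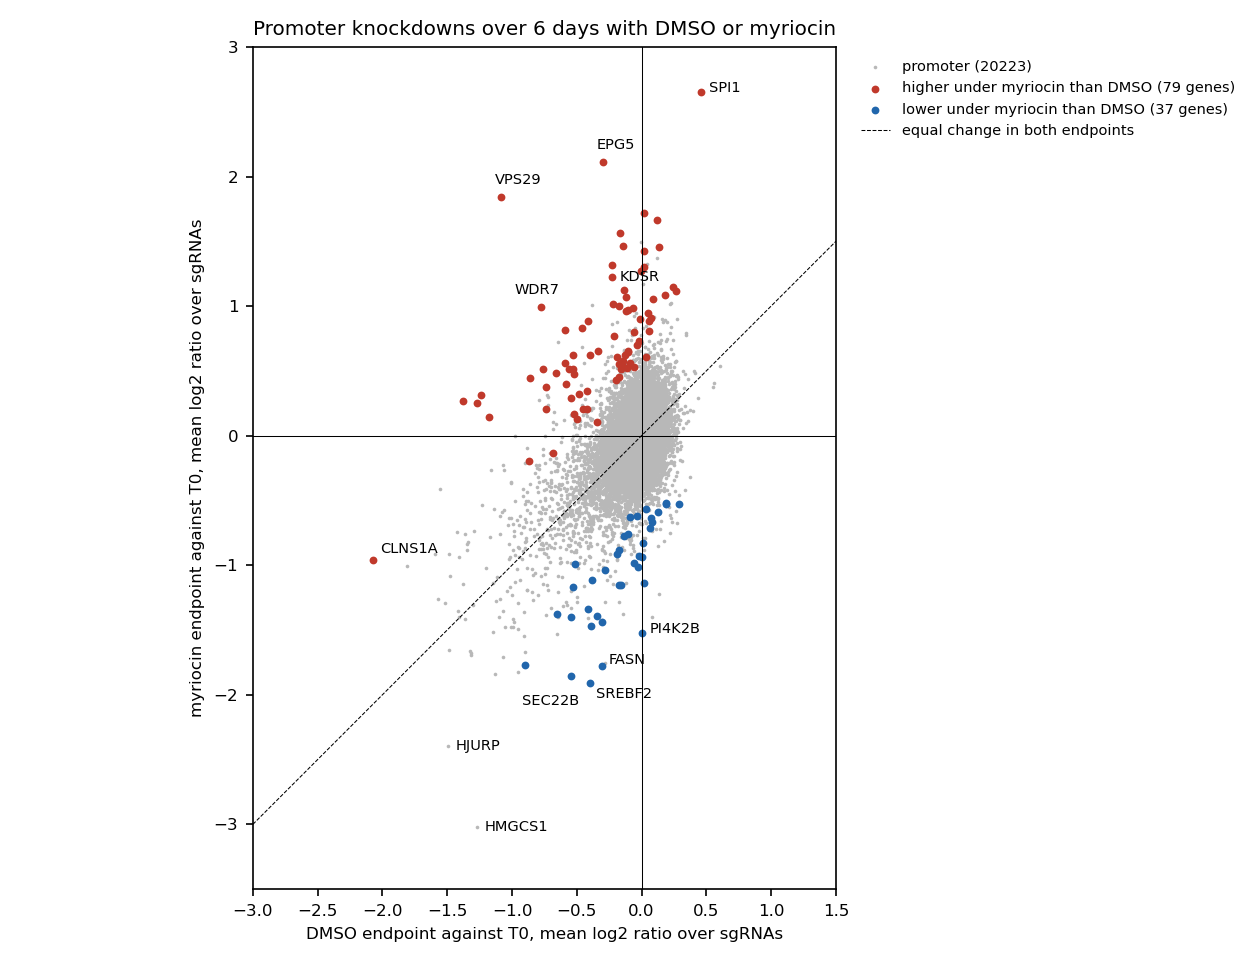
Mean log2 ratio to T0 of 20223 promoters at the DMSO endpoint (horizontal) and the myriocin endpoint (vertical), with genes that passed the test between the endpoints coloured and the dashed line marking equal change. VPS29 lies at −1.08 with DMSO and 1.84 with myriocin, and HMGCS1 at −1.27 and −3.02.

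The 79 genes that rose between the endpoints differed in how they grew without drug. VPS29 stood at −1.08 against T0 with DMSO and at 1.84 with myriocin, WDR7 at −0.78 and 0.99, EPG5 at −0.30 and 2.11, and SPI1 at 0.46 and 2.65. Of the 79, 64 lay below 0 in DMSO against T0 and 25 had passed the test there as lower; 76 lay above 0 in myriocin against T0 and 47 passed there. Of the 25, 3 were called higher against T0 under myriocin, 0 lower and 22 in neither direction. All 37 genes that fell between the endpoints lay below 0 in myriocin against T0, where 35 passed, and 7 had also passed as lower in DMSO. Such agreement arises partly because both comparisons use the myriocin library. Over control sets, which have no target, the 2 correlated at r = 0.87. Of the control sets called higher between the endpoints, 4 of 6 were also called higher in myriocin against T0, and of those called lower, 1 of 1 was also called lower.

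Against T0, 290 of 20241 promoters differed under myriocin, 78 higher and 212 lower, with 20 of 20000 control sets past the same p and 1972 promoters at an unadjusted p under 0.05. Of the promoters, 102 were lower with both DMSO and myriocin, against 4.30 for independent calls and 1 of 12 called control sets. Comparisons that share a library are not independent: across 20223 promoters the DMSO change from T0 and the myriocin to DMSO ratio correlated at r = −0.22 (Spearman −0.22), and over control sets, which have no target, at r = −0.28 (Spearman −0.26); promoters are not independent replicates, and the covariance beyond the control sets was −0.00399. Over 107 ribosome and proteasome promoters, the change under myriocin was 0.846 times that with DMSO (95% bootstrap interval 0.719 to 0.976), with the medians of both lists differing: −0.33 and −0.35 for the ribosome, −0.21 and −0.06 for the proteasome, with DMSO and with myriocin.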

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

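The alternatives with the controls of a promoter's own sublibrary and without repeated sgRNA sequences were chosen after the results were seen; the others were fixed before. No called result reversed direction. Counts are given as promoters changed, higher and lower for myriocin against DMSO (118, 81 and 37), DMSO against T0 (434, 23 and 411) and myriocin against T0 (290, 78 and 212). A permutation test of the mean gave 292, 181 and 111, then 892, 54 and 838, then 456, 119 and 337. Without the strongest sgRNA the counts were 52, 37 and 15, then 244, 12 and 232, then 115, 37 and 78. Fewer calls are built into this setting, since each promoter lost its largest absolute value while the control sgRNAs were left whole. Whether anything else contributed was not tested. The mean of the 3 strongest sgRNAs gave 184 changed and 64 lower for myriocin against DMSO, 860, 8 and 852 for DMSO against T0, and 183 changed and 23 higher for myriocin against T0, with the cause not tested. The stricter adjusted p of 0.01 by construction left 54, 39 and 15, then 250, 6 and 244, then 120, 37 and 83. Olfactory receptor sgRNAs as the background left 21 lower for myriocin against DMSO and 15 higher for DMSO against T0; the cause was not tested. Every other count of promoters stayed within 1.5 times its value, and scaling to total reads kept all calls: for promoters changed between the endpoints, the read minimums gave 101 to 117, a pseudocount of 10 gave 116, own sublibrary controls 109, no repeated sequences 117 and the residual on the DMSO change 118, of which 102 were among the 118 called without it. Of the genes named by the fixed rule, 22 of 39 called for myriocin against DMSO, 30 of 56 for DMSO against T0 and 10 of 10 for myriocin against T0 were called under every alternative; 27 of 101 uncalled genes for myriocin against DMSO and 32 of 83 for DMSO against T0 were called under at least 1. Of 21 genes named for myriocin against DMSO outside that rule, 2 of 12 called genes, DICER1 and ATP6V1C1, were called under every alternative, and 7 of 9 uncalled genes were called under at least 1. Of 120 list medians, taken over the 3 comparisons, 95 moved by more than their SE with the mean of the 3 strongest sgRNAs, 8 with a minimum of 20 reads and 5 with 100 reads. The mean of the 3 strongest sgRNAs is another measure on a larger scale, judged here by the SE of the original medians. Its 95 therefore follows largely from the definition and cannot be compared with the 8 and 5. Of the medians that moved, 6, 1 and 2 changed sign, none of them a list outside the central 95% of random lists. Matching random lists on growth moved 4 of 40 lists into that range and 4 out of it for myriocin against DMSO. Summing sequencing runs or taking each alone was not run, since each library has 1 column, and no paired analysis was possible because each condition has 1 library. Counting error does not set the limit, since it gives an SD of 0.11 in log2 ratio and the control sgRNAs 0.52 between the endpoints. The control SD still varied with reads per sgRNA across sublibraries. It was 0.46 for drug targets, kinases and phosphatases (median of 347 DMSO reads) and 0.62 for trafficking, mitochondria and motility (216), with the cause not tested. A uniform change of 0.5 was recovered for 38% of simulated promoters.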

Other observations

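The gene groups in the first paragraphs, and the tests on genes that rose between the endpoints after lying below 0 in DMSO, were chosen after the results were seen; the other tests were written down before their results.

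Knockdown of the cohesin complex, which holds sister chromatids and forms chromatin loops, gave higher values at the myriocin than at the DMSO endpoint. All 7 measured genes lay above 0 with a median of 0.60; RAD21 rose by 0.89 ± 0.23 (n = 10) and STAG2 by 0.84 ± 0.22 (n = 8), and 5 rose adjusted over the list alone. The 5 genes whose values had not been seen when the list was written had a median of 0.54, at percentile 99.98 of random lists, and none passed over all promoters. Of 7 microRNA processing genes (median 0.31), DICER1 rose by 1.29 ± 0.21 (n = 10), with DROSHA at 1.49 ± 0.45 and DGCR8 at 0.83 ± 0.34; the unseen members were at percentile 93.4. Of 8 genes of peroxisomal beta-oxidation (median 0.23), HSD17B4 rose by 0.88 ± 0.16 (n = 10), and the unseen members were at percentile 95.3. Of 10 methylosome and LSM genes 5 rose (median 0.54): LSM2, LSM6, CLNS1A (5 sgRNAs past the read minimum, against 7 in DMSO against T0), WDR77 and PRMT5. LSM6 had 7 sgRNAs past the read minimum, against 6 in DMSO against T0, and that minimum can raise values of genes depleted in DMSO. The list of 10 genes had fallen in DMSO against T0, with a median of −0.64 and 6 genes lower. It had a median of −0.06 with no call in myriocin against T0, and the unseen members were at percentile 60.5 between the endpoints.

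In trafficking, the 13 SNARE and p24 genes of the early secretory pathway had a median of −0.20 between the endpoints. SEC22B, TMED10 and USE1 fell, TMED2 stood at −0.63 ± 0.24, and the unseen members were at percentile 1.4. WDR7 was the 1 call among 4 rabconnectin-3 genes (median 0.46), with DMXL1 at 0.78 ± 0.36, and WDR11 the 1 call among 8 genes of its complex and golgin tethers (median 0.24), with C17orf75 at 0.65 ± 0.17. The unseen members of those lists were at percentiles 82.6 and 94.8. The WASH complex, which builds actin on endosomes, had a median of 0.26 (percentile 96.7, and 99.8 among lists matched on growth in DMSO) and no call among 6 genes. Of 12 genes of clathrin and its Golgi adaptors (median −0.07), CLTA and SCYL2 fell, with CLTC, the heavy chain, at −0.80 ± 0.34; the unseen members were at percentile 52.0.

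Of the 79 genes that rose between the endpoints, 64 lay below 0 in DMSO against T0, as chance reads of single sgRNAs or slower division under myriocin could give. Both were tested as sources of the rise by picking promoters on alternate sgRNAs and measuring them only on the others, each way on its own. The promoters picked were not all among the 64 genes. The median rise was 0.918 (95% bootstrap interval 0.621 to 1.10) over 28 promoters picked on odd sgRNAs and 0.547 (0.238 to 1.08) over 21 picked on even sgRNAs. Of these promoters 4 were picked both ways, and a rise of about 0 was predicted if chance in either library were its whole source. The DMSO change from T0, measured on the other sgRNAs, had medians of −0.314 over the 28 and −0.319 over the 21, below 0 there too. Slower division is unlikely as the whole source, since the rise left after the ribosome and proteasome slope of 0.846 was 0.866 (0.599 to 1.09) and 0.510 (0.187 to 1.07); of those lists the proteasome was nearer 0 under myriocin (median −0.21 with DMSO, −0.06 with myriocin) and the cytosolic ribosome was not (−0.33 and −0.35). For promoters also past the threshold as lower in DMSO, 12 and 7 of them, the rise was 0.801 (0.621 to 1.26) and 0.460 (0.0646 to 1.75) and the part left after the slope 0.763 (0.589 to 1.136) and 0.378 (−0.00237 to 1.63), so slower division is not excluded for these picked on even sgRNAs. Against T0 the myriocin change was 0.487 (0.342 to 0.684) over the 28 and 0.337 (−0.14 to 0.74) over the 21, and 0.349 (0.291 to 0.575) over the 12 and −0.14 (−0.32 to 0.88) over the 7; no biological explanation was tested, and a difference between the cultures stays open with 1 library per condition.

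VPS29, CCDC22, COMMD8 (1.31 ± 0.32) and COMMD10, of the retriever and Commander complexes, rose together between the endpoints. VPS29 is also a subunit of the retromer, so its rise cannot be assigned to the retriever and Commander complexes alone. Without drug VPS29 differed from the others, at −1.08 in DMSO against T0 where CCDC22, COMMD10 and COMMD8 stood at 0.016 to 0.14. The 4 do not all belong to the same sublibrary, so noise in 1 sublibrary could not raise all 4 by design. Each of the 4 passed against the control sgRNAs of its own sublibrary (exact test, adjusted p from 2.44e-11 to 0.0110), so wider noise there is unlikely as the source. Knockdown of a neighbouring gene is also unlikely, since 0 of the 4 have another called promoter within 1 kb. The other 11 Commander genes had a median of 0.24, at percentile 99.83 of random lists. Of them 9 lay above 0, and COMMD7 (−0.31) and DSCR3 (−0.27) below. Adjusted over the list alone 3 were higher, and none over all promoters. These values are in line with a response shared by the complex as a hypothesis, found and tested on the same libraries; a difference between the cultures stays open, with 1 library per condition.

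Cholesterol synthesis genes were lower at the myriocin than at the DMSO endpoint, with a median of −0.30 over 21 genes. The median was at percentile 0 of random lists matched on the DMSO change from T0. That match cannot decide whether the growth loss that these knockdowns also cause without the drug is the whole source. It shares the DMSO library with the ratio tested, and over control sets the 2 correlated at r = −0.28, which tends to lower the percentile of a depleted list. Unmatched, the spliceosome, DNA replication and both ribosome lists, with DMSO medians from −0.37 to −0.29, had medians from −0.0013 to 0.14 between the endpoints. The COG complex, with a DMSO median of −0.21, was lower, at −0.23. Without the 3 lowest cholesterol synthesis genes the median of 18 genes was −0.24, at percentile 0.01 of lists matched in the same way, with 14 below 0. This could not test whether a few members make the pattern, since a median with 17 of 21 genes below 0 stays below 0 without 3 of them. The 17 genes show that values below 0 were not limited to a few members, though 2 passed over all promoters and 8 adjusted over the list alone. That cells under myriocin depend more on making their own cholesterol in de-lipidated medium may account for the lower values, as a hypothesis that was not tested. No medium with lipids was compared, so the part played by the medium was not tested either.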
